A study of Homo sapiens with 2 samples.

How the data were processed

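Poly(A) RNA of the ARP1 myeloma line was sequenced as paired ends, per the labels' protocols, giving 1 library labelled siVCP and 1 labelled siNC. The deposited table holds FPKM values and estimated counts per gene for both libraries. The submitters' processing notes name HISAT2 2.0 and StringTie 1.3.0, without a role or order. The genome build and annotation were not given in the sources used here. Of the gene identifiers, 58394 were in GENCODE 29, and 90.6% of those had the same start or end there on GRCh38, so coordinates are given as GRCh38. The strandedness of the library was not given in the sources used here, so reads of genes that overlap on opposite strands cannot be told apart.

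FPKM values were normalized by the authors, and rows with a count of 0 carry a small floor value, which was set to 0. The counts deposited by the authors are whole numbers, but low values pile up at multiples of 4 (1205 rows at 4 counts in the library labelled siVCP, against 417 at 3 and 244 at 5). From this it was inferred, not stated by any source, that 1 fragment adds about 4 counts. Intervals were therefore computed from counts divided by 4 as exact conditional binomial 95% intervals of the ratio, scaled to the FPKM fold. They cover counting error only, and reads without molecular identifiers are not independent molecules. The floor of a count of 0 was 3 fragments, 12 counts, per library.

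Rows that share a symbol were summed. The log2 ratio was log2((FPKM labelled siVCP + 1)/(FPKM labelled siNC + 1)), which understates the difference of low genes, and folds are plain FPKM ratios. Genes with an FPKM of at least 1 in at least 1 library were used. No count model and no test were run, because each group has 1 library. The design had allowed for FPKM or counts, and FPKM was used for the main values.

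The 29 gene lists (22 response lists and 7 marker lists of other cell types), the thresholds, the rule for named genes and the first set of other settings were fixed before the data were examined. For each response list the number of members at least 1.5-fold higher or lower on the log2 ratio scale was counted, and the median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A percentile describes these libraries and is no test. Named genes were VCP, the 15 highest and 15 lowest log2 ratios among genes with an FPKM of at least 5 in a library, passing over uncharacterised loci and pseudogenes, up to 3 highest and 3 lowest members of each list, and the highest member of each marker list. In lists of cofactors, stress sensors or named markers the rule also allowed any other member given as a value. This applies to DERL2, YOD1, HSPA5, XBP1, SDC1, IRF4, JCHAIN and CD38. A few genes that this rule selects are not reported here. CBS (the partner of CBSL), PSMA6 and CIITA were added after their values were seen.

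Settings fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter at FPKM 5, rescaling to the same sum or to a median ratio of 0, the highest row per symbol, thresholds of 1.5-fold and 4-fold, unmatched random lists, and CPM from the counts with median-ratio size factors. Chosen after seeing the data were genes not merged by symbol, rows with a protein-coding transcript, genes without a same-strand overlapping row, and random lists matched on transcript length and GC content (6 bins each, longest basic protein-coding transcript of GENCODE 29, which 83.1% of the genes and every list member had).

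The steps were tested on simulated data drawn with Poisson counting error. In simulated unchanged libraries 44 of 11379 genes were at least 2-fold apart, against 275 observed. Of 200 genes changed 2.5-fold, all drawn from genes with an FPKM of at least 5 in both libraries, 96.5% passed 2-fold in the right direction. Recovery among lower genes was not simulated. In simulated data, 3 of 100 unchanged lists fell in either 2.5% tail. Their genes varied independently, without a trend with transcript length or GC content, so this share need not hold for real lists. A planted 3' UTR word that lowered its genes by 0.2 (log2) was found as the lowest score in 20 of 20 trials. Smaller shifts were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.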

Results

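Gene expression was measured by poly(A) RNA sequencing in ARP1, a cell line derived from multiple myeloma, a cancer of plasma cells. One library was labelled siVCP (VCP knockdown) and 1 was labelled siNC (control). VCP encodes p97, an ATPase that extracts ubiquitin-marked proteins from membranes and complexes and hands them to the proteasome. The comparison asks which transcripts differ when VCP is knocked down. Counts summed to 68872657 in the library labelled siVCP and to 72566092 in the library labelled siNC. Of 60612 gene rows, which carried 50229 symbols, 11645 symbols reached an FPKM of 1 in at least 1 library. With 1 library per group there was no replicate error, no test and no p-value. Every difference below is between these 2 libraries, and intervals in brackets are 95% intervals that cover counting error only.

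VCP itself went against its label. VCP (ENSG00000165280; GRCh38 coordinates chromosome 9, 35056064 to 35072627, minus strand) had an FPKM of 65.9 in the library labelled siVCP and 47.7 in the library labelled siNC. The counts were 26192 and 20004. The library labelled siVCP was therefore 1.38-fold higher [1.33 to 1.43], a log2 ratio of 0.46. The targeted transcript was not lower in the library labelled as its knockdown, so each direction below refers to the library labels and not to a shown loss of VCP. Among 29 measured genes of VCP and its cofactors, on the log2 ratio scale 1 was at least 1.5-fold higher and 0 were at least 1.5-fold lower. The median log2 ratio of that list was -0.07, at percentile 18.4 of random lists matched on expression. The ubiquitin-binding cofactor pair had log2 ratios of 0.58 for UFD1 and 0.49 for NPLOC4, and NSFL1C (p47) had 0.83. RHBDD1 had -0.56, VCPIP1 -0.54 and ZFAND1 -0.53.

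**Figure D1:**
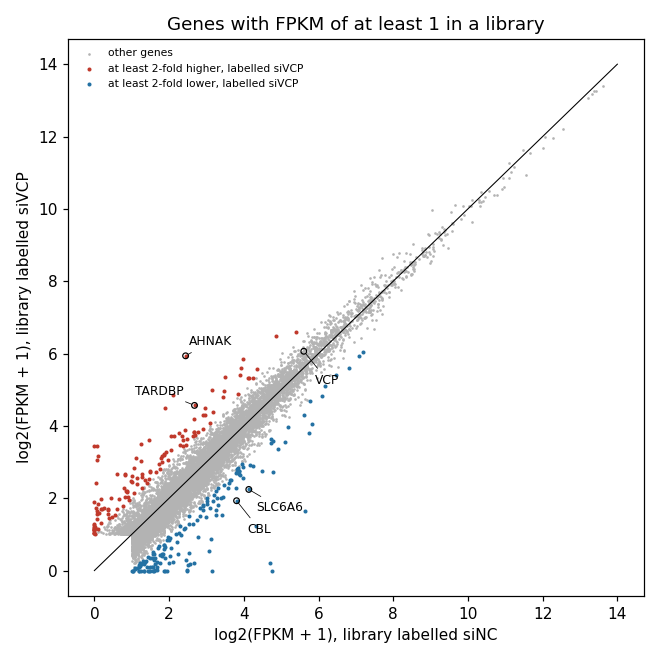
FPKM of each measured gene (1 point per gene symbol) in the library labelled siNC (x axis) and the library labelled siVCP (y axis), both as log2(FPKM + 1), with the line of equal values. Red and blue points are the 122 and 153 genes at least 2-fold higher and lower in the library labelled siVCP, and VCP lies above the line, at FPKM 65.9 against 47.7.

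Most genes had similar values in both libraries. In the library labelled siVCP, 122 genes were at least 2-fold higher and 153 were at least 2-fold lower, together 2.36% of those measured. The counts depended on the settings. With a pseudocount of 0.1 they were 260 and 426, and with a pseudocount of 5 they were 29 and 25, so that the higher genes became the larger group. After rescaling both libraries to the same sum, which also let 15172 genes pass the filter, they were 390 and 571. Without genes that overlap another row on the same strand they were 69 and 85. Simulated unchanged libraries with counting error alone gave 44 such genes. AHNAK, which encodes a very large scaffold protein, had the highest log2 ratio among the named genes, with FPKM 60.3 against 4.43, a 13.6-fold difference [13.0 to 14.3]. TARDBP, which encodes the RNA-binding protein TDP-43, was 4.19-fold higher [3.84 to 4.59]. RAB5B, a small GTPase of early endosomes, was 7.61-fold higher [6.54 to 8.88], and M6PR, a receptor that sorts lysosomal enzymes, was 3.38-fold higher [3.16 to 3.62]. The methylglyoxal-detoxifying enzyme gene GLO1 was 3.83-fold higher [3.48 to 4.22]. TSN (3.90-fold), the nucleotide receptor gene P2RY6 (7.02-fold), DIRAS1 (10.2-fold) and the long noncoding RNA OIP5-AS1 (5.20-fold) completed the higher genes with a row that is neither a read-through, a small RNA nor a gene copy. OIP5-AS1 and M6PR overlapped OIP5 and PHC1, and DIRAS1, RAB5B and AHNAK overlapped unnamed loci.

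On the lower side, the taurine transporter gene SLC6A6 had FPKM 3.73 in the library labelled siVCP and 16.6 in the library labelled siNC, a log2 ratio of -1.89. CBL, a ubiquitin ligase acting on receptor tyrosine kinases, had a log2 ratio of -1.88, and the ubiquitin ligase gene CBLL1 had -1.83. CDPF1 had -2.24, the septin gene SEPTIN11 -1.73, PRXL2B -1.71, FAM102A -1.58 and RAP1GAP2 -1.52. ABHD14B (-1.56) overlapped PCBP4, and the noncoding RNA DANCR (-1.40) overlapped small RNA rows. CBL overlapped MCAM.

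Several of the most different rows overlap another row, are copies of another gene or are short RNAs, and their values are uncertain. Reads assigned to more than 1 row were not measured here. The read-through row RPL17-C18orf32 had 1250 counts against 0, at least 110-fold higher against a floor of 12 counts. CORO7-PAM16 was 6.46-fold higher, and SENP3-EIF4A1 had a log2 ratio of -2.04. CBSL, a copy of CBS, was 8.42-fold higher, whereas CBS had a log2 ratio of 0.21. HNRNPA1L2, a copy of HNRNPA1, had a log2 ratio of -1.50. The short RNA rows SNORA58B (83 against 1 counts), RNVU1-7 (73 against 12), MIR4444-2 (38 against 7), MIR4707 (1 against 181) and SNORD32A (2 against 40) rested on few counts. A further 6 higher and 9 lower rows within this ranking were uncharacterised loci or pseudogenes. Of the 275 genes at least 2-fold apart, 44.0% overlapped another row with a count on the same strand, against a median of 24.0% in random gene sets matched on expression. On either strand the share was 64.7% against 55.6%.

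Genes for proteasome subunits were the most shifted of the 22 response lists. All 37 were measured, 34 had a log2 ratio above 0, 20 were at least 1.5-fold higher in the library labelled siVCP and 0 were at least 1.5-fold lower. Their median log2 ratio was 0.59 above all 10000 random lists matched on expression. The regulatory-particle gene PSMD11 was highest (2.07-fold [1.96 to 2.18]), and by log2 ratio ADRM1 (0.87), PSMC4 (0.85) and the core-particle gene PSMA6 (0.84) followed. By plain FPKM fold, PSMA6 (1.86-fold) stood above ADRM1 (1.85-fold) and PSMC4 (1.82-fold). PSMD9, PSME4 and PSMA2 had log2 ratios of -0.11, -0.11 and -0.05. The list is wider than the subunits of the assembled proteasome, since PSMD5, PSMD9, PSMD10 and POMP encode assembly factors and PSME4 an activator.

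**Figure D2:**
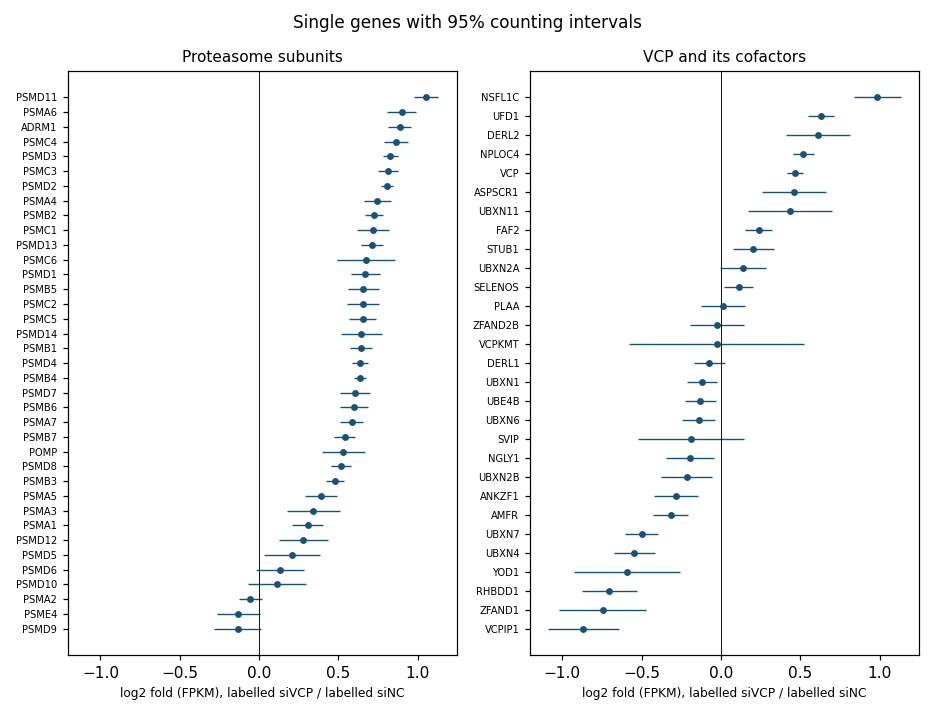
Log2 FPKM fold (library labelled siVCP over library labelled siNC) of each measured gene of the proteasome subunit list (left, 37 genes) and of VCP and its cofactors (right, 29 genes), with 95% counting intervals as bars. On the left, 34 of the 37 points lie above 0, and on the right the points spread to both sides of 0.

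Heat shock proteins and their cochaperones were also higher in the library labelled siVCP, with a median log2 ratio of 0.39 over 18 genes (percentile 99.99) and 4 genes at least 1.5-fold higher. DNAJB1 was 1.80-fold higher [1.69 to 1.93], the constitutive chaperone gene HSPA8 1.71-fold and the mitochondrial co-chaperonin gene HSPE1 1.56-fold. In contrast, HSPA4 had a log2 ratio of -0.34 and the mitochondrial chaperonin gene HSPD1 one of -0.08. The NRF2 oxidative stress list had a median of 0.26 over 17 genes (percentile 99.4) but 1 member at least 1.5-fold higher on this scale, PIR, at 2.48-fold. NQO1 had a log2 ratio of 0.55 and HMOX1 -0.09. Without a filter on low values the median was 0.17, at percentile 97.0. Cholesterol synthesis genes had a median of 0.26 over 22 genes (percentile 99.9), with 1 member, ACAT2, at least 1.5-fold higher on the log2 ratio scale. By plain FPKM ratio ACAT2 was 1.59-fold and IDI1 1.52-fold higher. IDI1 and FDPS had log2 ratios of 0.48 and 0.49.

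In all, 6 lists lay in the lower 2.5% of random lists. Genes of the G2/M phase and mitosis had a median of -0.19 over 27 genes, below all 10000 random lists, of which 5 were at least 1.5-fold lower. The proliferation marker MKI67 had a log2 ratio of -1.22, the kinetochore gene CENPF -0.95 and TOP2A -0.83, while CCNB1 (0.30), CDC20 (0.24) and PLK1 (0.23) were on the other side of 0. With an FPKM of at least 5 the median was -0.11. Hypoxia and glycolysis genes had a median of -0.23 over 24 genes (percentile 0.070). In that list 10 were at least 1.5-fold lower, among them ANKRD37 (-1.17), the mitophagy receptor gene BNIP3L (-1.12) and KDM3A (-0.91). The glycolytic enzyme genes TPI1 (0.94), ENO1 (0.43) and GPI (0.42) had ratios above 0. Without genes that overlap another row on the same strand, the median of this list was -0.59 over 16 genes, and with an FPKM of at least 5 it was -0.07, at percentile 14.1. It was -0.11, at percentile 3.14, without a filter and -0.12 with a pseudocount of 5.

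Interferon-stimulated genes had a median of -0.49 over 9 measured genes (percentile 0.030), all 9 below 0. OAS1 had -0.58 and OAS2 -0.55, and IFI6, at -0.61, was the single member at least 1.5-fold lower. Without a filter the median over 25 genes was -0.0083, at percentile 13.2, and with a pseudocount of 5 it was -0.22. Replication-dependent histone genes had a median of -0.36 over 11 genes (percentile 0.16), led by H1-2 (-0.69) and H2BC11 (-0.65), and of -0.16 without a filter and -0.21 with a pseudocount of 5. Histone transcripts largely lack a poly(A) tail, which this library preparation selects. Mitochondrially encoded mRNAs had a median of -0.17 (percentile 0.39), with 12 of 13 below 0, MT-ND6 lowest at -0.40 and MT-ND1 at 0.16. Cytosolic ribosomal protein genes had a median of -0.06 over 50 genes (percentile 0.51), with RPL23 at -0.40 and RPL15 at 0.63. Against lists not matched on expression the last 2 lists stood at percentiles 8.46 and 23.1. The ribosomal protein median was -0.00078 with CPM from the counts, and its percentile was 3.69 with an FPKM of at least 5 and 4.07 without same-strand overlaps.

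**Figure D3:**
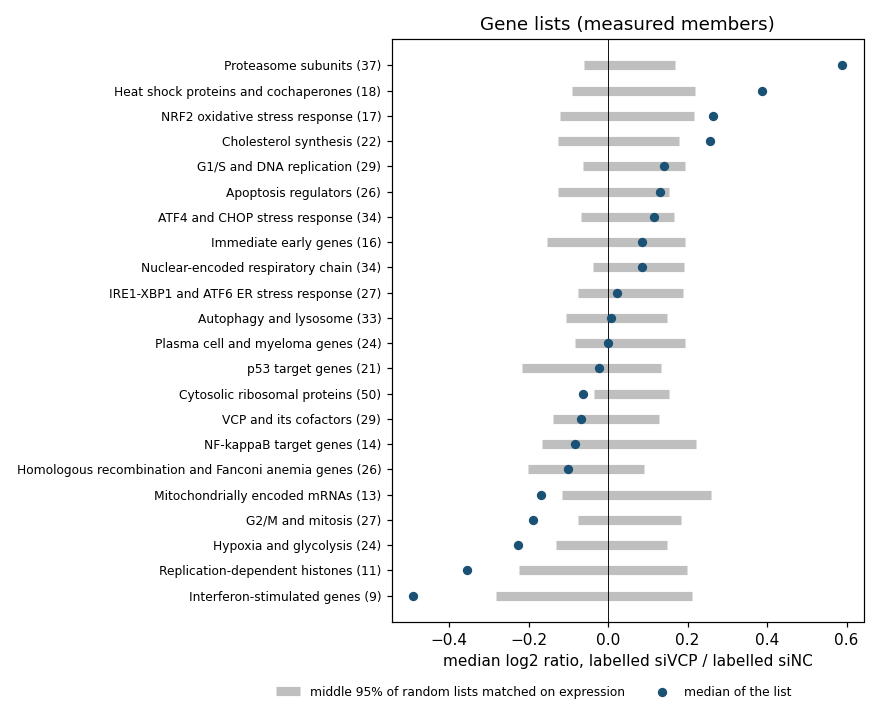
Median log2 ratio (library labelled siVCP over library labelled siNC) of each response list as a point, with the middle 95% of 10000 random lists matched on expression as a grey bar and the number of measured genes in brackets. Proteasome subunits stand farthest to the right, at 0.59, and interferon-stimulated genes farthest to the left, at -0.49.

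The lists for the integrated stress response and ER stress lay within the middle 95% of random lists matched on expression. Against unmatched lists the ATF4 and CHOP list lay outside it, at percentile 98.0, and its median was 0.19 with CPM from the counts. The ATF4 and CHOP list had a median of 0.12 over 34 genes (percentile 87.8), with 4 genes at least 1.5-fold higher and 2 lower. CHAC1 was 2.19-fold higher [1.81 to 2.65], ATF4 1.63-fold higher, and ATF5 had a log2 ratio of 0.83, whereas DDIT3, which encodes CHOP, had a log2 ratio of -0.61, ATF3 -0.65 and DDIT4 -0.58. The IRE1-XBP1 and ATF6 list had a median of 0.02 over 27 genes and a mean of -0.01 (percentile 30.2). The ER chaperone gene HSPA5 had a log2 ratio of 0.24, DERL3 0.60, ERN1 -0.47 and DNAJB9 -0.53. Autophagy and lysosome genes had a median of 0.01 over 33 genes (percentile 45.3), with 2 higher (CTSD at 0.87, ATG16L1 at 0.71) and 3 lower, among them CTSB at -0.82, and SQSTM1 at 0.58.

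The p53 target genes had a median of -0.02 over 21 genes (percentile 57.4) and a mean of -0.18. None was at least 1.5-fold higher and 4 were lower, among them TP53INP1 (-0.99), CCNG1 (-0.98) and ZMAT3 (-0.86). By plain FPKM ratio they were 6.30-fold, 2.01-fold and 5.10-fold lower. TP53INP1 and ZMAT3 were low in the library labelled siNC too, at FPKM 1.44 and 1.27. Apoptosis regulators had a median of 0.13 over 26 genes (percentile 95.2) and a mean of -0.01, with 2 higher and 5 lower. In that list BCL2 had a log2 ratio of -0.90 and BBC3 -0.75, against 0.83 for DIABLO, 0.59 for CASP6 and 0.51 for BCL2L1. Its percentile was 97.8 against unmatched lists, and its median was 0.21 both with an FPKM of at least 5 and with CPM from the counts. NF-kappaB target genes had a median of -0.08 over 14 genes (percentile 13.6), with TNFAIP3 at -0.72 and NFKBIA at 0.43. G1/S and DNA replication genes had a median of 0.14 over 29 genes (percentile 88.5), with FEN1 at 0.60, CCNE1 at 0.53 and POLA1 at -0.43. They stood at percentile 98.8 against unmatched lists, and their median was 0.21 with CPM from the counts. Homologous recombination and Fanconi anemia genes had a median of -0.10 over 26 genes (percentile 27.7). On the log2 ratio scale 1 was lower, RAD50 at -0.61, with BRCA1 at -0.55 and XRCC3 at 0.48. By plain FPKM ratio ATM (2.12-fold), BRCA1 (1.70-fold) and RBBP8 (1.57-fold) also passed 1.5-fold lower, and XRCC3 (1.58-fold) passed 1.5-fold higher. The direction of that median turned to 0.026 with an FPKM of at least 5, and it was -0.20 after rescaling to the same sum and -0.024 without same-strand overlaps. Nuclear-encoded respiratory chain genes had a median of 0.08 over 34 genes (percentile 60.8), with NDUFB8 at 0.46 and NDUFV1 at -0.36, and a median of 0.15 with CPM from the counts. Immediate early genes had a median of 0.09 over 16 genes (percentile 79.5), with ZFP36 2.99-fold higher [2.68 to 3.34], KLF6 2.10-fold higher and KLF2 at -0.85.

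Plasma cell and myeloma genes had a median of -0.00 over 24 genes (percentile 22.03). Both libraries expressed XBP1 (FPKM 434 and 437 in the libraries labelled siVCP and siNC), SDC1 (257 and 223) and IRF4 (186 and 178). The transcription factor gene MAF was the member at least 1.5-fold lower on the log2 ratio scale, at -0.89, and SLAMF7 had 0.57. The list mean was -0.11, with 12 members above 0 and 12 below. Among those below 0 were PRDM1 (-0.57), ITGA4 (-0.56), JCHAIN (-0.55) and CD38 (-0.47). Markers of T cells, myeloid, stromal, epithelial and erythroid cells had an FPKM of at most 2.51 in either library. The highest T cell marker was TRAC (FPKM 1.55 and 2.51), the highest myeloid marker CD68 (1.10 and 1.41), the highest stromal marker FN1 (0.774 and 0.927), the highest epithelial marker KRT18 (1.66 and 1.61) and the highest erythroid marker HBA1 (0.385 and 0.564). PPARG, the highest of the adipocyte markers, had 7.64 and 8.84. Of the earlier B cell markers, CD79A, at 2.36 and 4.94, was highest in the library labelled siNC, and CIITA, at 3.73 and 4.82, was above it in the library labelled siVCP.

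Log2 ratios also followed transcript length and GC content across genes. Over 9674 genes, Spearman's rho was -0.26 with length and 0.30 with GC content, across genes that are not independent replicates. The median log2 ratio was 0.08 in the fifth of genes with the shortest transcripts and -0.16 in the fifth with the longest. Against random lists matched on length and GC content, the proteasome list stayed at percentile 100 and the heat shock list at 99.99, the G2/M list stood at 1.04 and the hypoxia and glycolysis list at 0.040. G1/S genes stood at 96.1 and apoptosis regulators at 97.6.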

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

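The settings without merging by symbol, with protein-coding rows, without overlaps and with lists matched on length and GC content were chosen after seeing the data. No paired analysis was possible because each group held 1 library, and for the same reason no library could be left out. None of the list medians outside the middle 95% of random lists, nor the VCP ratio, changed sign under any alternative run. VCP moved under 1 alternative, to 0.53 with CPM from the counts, and stayed within its counting interval under 10. Of the 242 list medians and 286 list percentiles recomputed, 220 and 274 kept their place. Values of named genes were less stable, with 109 of 310 moved and 201 not. Of the 26 counts of genes recomputed, 16 moved and 10 did not. The counts of genes at least 2-fold higher and lower were 122 and 153. They were 260 and 426 with a pseudocount of 0.1, 29 and 25 with 5, 68 and 71 with an FPKM of at least 5 (6245 genes in place of 11645), 390 and 571 after rescaling to the same sum (15172 genes, since the filter and the pseudocount stayed at 1 on a larger scale), 528 and 684 at 1.5-fold, 12 and 15 at 4-fold, 66 and 86 over rows with a protein-coding transcript, and 69 and 85 without same-strand overlaps. The last 2 of these settings tested 9683 and 8916 genes. With a pseudocount of 5, medians were 0.52 for proteasome subunits, -0.22 for interferon-stimulated genes, -0.12 for hypoxia and glycolysis and -0.21 for histones. Without a filter, which adds unexpressed members, they were 0.17 for NRF2 (percentile 97.0), -0.0083 for interferon-stimulated genes (13.2), -0.11 for hypoxia and glycolysis (3.14) and -0.16 for histones. With an FPKM of at least 5 they were 0.21 for apoptosis regulators, -0.11 for G2/M, 0.026 for homologous recombination and -0.073 for hypoxia and glycolysis (14.1), and ribosomal proteins stood at percentile 3.69. After rescaling to the same sum homologous recombination was at -0.20. With CPM from the counts, which raised the median of all genes from -0.02 to 0.03, medians were 0.19 for ATF4 and CHOP, 0.70 for proteasome subunits, 0.21 for apoptosis regulators, 0.21 for G1/S, 0.37 for cholesterol synthesis, 0.15 for the respiratory chain and -0.00078 for ribosomal proteins. Without same-strand overlaps homologous recombination was at -0.024, hypoxia and glycolysis at -0.59 and ribosomal proteins at percentile 4.07. Against unmatched lists, ATF4 and CHOP stood at 98.0, apoptosis regulators at 97.8, G1/S at 98.8, mitochondrial mRNAs at 8.46 and ribosomal proteins at 23.1. Matched on length and GC content, apoptosis regulators stood at 97.6. The medians near 0 of p53 targets and of plasma cell genes changed sign with CPM from the counts, to 0.028 and 0.061, the autophagy median did so without a filter, at -0.012, and the homologous recombination median with an FPKM of at least 5, as given. The cause of the list differences was not tested beyond what each setting removes or adds. Depth limits rows with few counts, such as the small RNA rows.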

Other observations

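The pathway groups, the scaling tests and the reading of word shifts in this part were chosen after the results were seen. Beyond the fixed lists, 285 pathways of the deposited annotation with at least 10 measured genes were placed among matched random lists, and 7 lay in the upper 2.5%, about the number chance alone gives, and 37 in the lower 2.5%. Pathways can share genes, so these are not separate observations. On the lower side type I diabetes mellitus, allograft rejection and graft-versus-host disease had the same median, -0.395266. Matched on length and GC content instead, some lower pathways left the lower 2.5%. Focal adhesion went from percentile 2.41 to 29.4 and cellular senescence from 0.29 to 9.51. Others, such as systemic lupus erythematosus and cell adhesion molecules, stayed at 0. Besides the proteasome, genes of the spliceosome (128 genes, median log2 ratio 0.19, percentile 100), of ribosome biogenesis (74 genes, 0.17, percentile 99.99) and of RNA polymerases (31 genes, 0.20, percentile 99.4) had medians on the higher side in the library labelled siVCP. At least 1.5-fold higher and lower were 4 and 3 spliceosome genes, 9 and 1 ribosome biogenesis genes and 3 and 1 RNA polymerase genes. PUF60 and U2AF2, which help define splice sites, had log2 ratios of 0.75 and 0.58, while SYF2, of the same pathway, had -1.04. In the other groups, NOP56 of the small nucleolar ribonucleoproteins had 0.74 and RPP38 had 1.18. Matched on length and GC content, the spliceosome and ribosome biogenesis groups stood at percentile 100.

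Antigen presentation genes lay on the lower side (45 genes, median log2 ratio -0.13, percentile 0.070), as did cell adhesion molecules (46 genes, -0.24, percentile 0). In the first group 5 were at least 1.5-fold lower and 2 higher, PSME3 (1.23) and HSPA8 (0.77), and in the second 2 were lower and 0 higher. CD74, the invariant chain of class II molecules, had a log2 ratio of -1.12, with FPKM 5.75 in the library labelled siVCP against 13.7. HLA-E had -0.60, HLA-B -0.47 and B2M -0.34, whereas HLA-C had 0.03. The integrin gene ITGB1 had -0.80. HLA genes share sequence with each other, so their single values are uncertain.

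VCP was higher in the library labelled siVCP, at a log2 ratio of 0.46. The lowest log2 ratio over 4 ways of scaling was 0.46. These left the median of all genes between -0.03 and 0.03, too little to bring VCP to 0, so that comparison decides nothing. No row overlaps VCP on either strand (0 counts in the library labelled siNC to move), which argues against reads moved from overlapping rows. An exchange of the 2 libraries cannot be told apart from a knockdown that did not lower the transcript at sampling. The stress lists that were to decide stood at percentiles 87.8 (ATF4 and CHOP) and 30.15 (IRE1-XBP1 and ATF6), neither both above 95 nor both below 5. A biological change of VCP in the treated cells also stays open and was not tested.

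Proteasome subunit genes were higher in the library labelled siVCP, and a trend with transcript length and GC content does not account for it. Their median stayed at percentile 100 of lists matched on transcript length and GC content. Its lowest value over the scalings was 0.59. A scaling shifts all genes nearly alike, so it could hardly change the place of the list among random lists, and that comparison decides nothing. A hypothesis written before its value was seen was that assembly and ubiquitin shuttle factors are higher too. That list of 20 genes had a median log2 ratio of 0.20, at percentile 98.23, with 16 above 0 and 3 at least 1.5-fold higher, among them ZFAND5 (1.83-fold) and NFE2L1 (1.61-fold), while PSMG2 had -0.35 and NFE2L2 -0.21, so a joint rise may hold for part of the list in these libraries. With 1 library per group a difference between cultures unrelated to the siRNA stays open.

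Seed matches of a transfected siRNA were tested through 7-base words in the 3' UTRs of 5586 genes, after adjusting for length, GC content and expression. By the criterion written beforehand the result was positive, since GGCTGAG, the word with the most extreme score (5.49), lay beyond all 100 shuffles (5.17 at most) and the other 206 words of its base composition (5.41 at most, GGTCAGG), whose median of 0.999 argues against base composition as the source. The margin is small, 15 word scans were tried in all, genes with the word were higher by only 0.06 on average, and the lowest score (-4.52) was within the shuffles (-4.55). Other words scored nearly as high, among them GGGAGGC (5.16), GGAGGCT (4.48), which overlaps it, AGGCAGG (4.68) and CAGTGAG (4.91). GGGAGGC, GGAGGCT and GGCTGAG overlap in turn, as pieces of a longer stretch would. A seed of 7 bases alone would not predict such a set unless the words occur in the same 3' UTRs, which was not tested. The scan cannot tell words carried together by a common repeat from a seed. Such a seed would belong to the siRNA that the library labelled siNC received, whichever it was. A repeat was not tested, and neither siRNA sequence was used here.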
